A study of Mus musculus with 2 samples.

How the data were processed

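The 2 small RNA libraries of mouse neural tube at E11.5 were made from 1 pool of embryos each and belong to a single group. The replicate numbers are those of the labels. The deposited values were raw read counts per miRNA gene for the mm10 assembly and the GENCODE M4 annotation, per the file headers. Each library had 3 columns of counts with no column names. They were read as reads on either strand, on the gene's own strand and on the opposite strand, from their layout and values. The first summed to the other 2 in both libraries (3787129 to 3708662 and 78467 in replicate 1, 4124504 to 4055883 and 68621 in replicate 2). The aligner, the counter and any trimming of adapters are not given in the sources used here. The own-strand counts were used, since libraries made by ligating adapters to small RNA read the strand of the RNA. The number of per-sample columns that could not be tied to a sample was 0.

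Reads that named no gene stood in separate rows and were left out of library totals and tests. They formed 56.5% of reads in replicate 1 and 47.0% in replicate 2. Unmapped reads were 24.5% and 15.2%, and reads mapped to several places 25.2% and 27.3%. Mapped reads that lay on no gene's own strand were 6.83% and 4.49%, and ambiguous reads 0 in both. The mapped reads on no gene's own strand include those on the opposite strand of a gene. Own-strand gene counts came to 43.5% and 53.0% of reads. Reads mapped to several places were thus held back from the genes. Where several genes carry the same mature miRNA, such as the copies of Mir9, Mir124a and let-7a, the gene counts can leave reads of that miRNA out, and how many was not analysed here.

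Gene symbols, coordinates, host genes and hairpin sequences came from GENCODE M21 (GRCm38), matched by gene identifier. Of 1973 genes, 1894 matched, and the 79 others held 4 own-strand counts over both libraries. M21 holds 2202 miRNA genes, of which 308 had no row used here. Counts are per hairpin gene, so the 2 arms of a hairpin were not told apart. A gene was called uncertain when its hairpin shared a run of at least 20 nt with another hairpin of the annotation, as 923 genes did.

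CPM was the own-strand count divided by the sum of own-strand counts on miRNA genes and multiplied by 1000000. List shares are percentages of that sum with 95% Wilson intervals, which treat reads as independent and cover counting error only, since no molecular identifiers are stated. The 15 gene lists, the tests of the report and the rule for named genes were fixed before the data were examined. The lists were neural, glial and late neuronal, Hox cluster, let-7 family, pluripotency, miR-17 clusters, Dlk1-Dio3 imprinted, muscle, blood, endothelial, mesenchyme, epithelial and sensory, liver, gut and endocrine, X-linked testis cluster and Sfmbt2 cluster. The last took every gene named Mir297, Mir466, Mir467 or Mir669, some of which lie elsewhere. Named genes were the 25 with the highest mean CPM, up to 4 of each list by mean CPM with at least 10 summed counts, and up to 5 per direction by ratio among genes that passed the test, had a mean of at least 100 counts and differed at least 2-fold. Genes of the closing part that lie outside this rule were chosen after their values were seen.

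No test between groups exists with 1 group. Each gene's counts in the libraries were compared by a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment over the 444 genes with at least 10 summed counts and a threshold of 0.05. Log2 ratios carry a pseudocount of 0.5 counts, and correlations used log2(CPM + 1). The test sets the distance between 2 libraries against counting noise and takes reads as independent, so copies made by PCR make its p-values too small. The libraries were treated as 2 replicates because the labels name separate pools. Their counts were not identical, with 236 genes past the test. The test cannot tell separate pools from preparations of the same pool, so these calls do not bear on that choice. A list's median log2 ratio was placed among 10000 random lists of the same size matched by decile of mean CPM. TMM factors and the common dispersion came from edgeR 4.0.16 and size factors from DESeq2 1.42.0, under R 4.3.3, and the rest was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Chance differences between counts of 100 per library have an SD of 0.20 on the log2 scale.

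The test was tried on simulated counts for these genes and library sizes with 200 genes changed. It recovered 69% of genes changed 1.5-fold (442 tested), 76% of those changed 2-fold (447 tested) and 91.5% of those changed 4-fold (445 tested). Among genes with at least 200 counts it recovered 98.4% at 1.5-fold and 100% at 2-fold and 4-fold. False calls were 4.17%, 2.56% and 2.66% of calls at these folds, and 0 of 442 genes were called without a change. The simulated counts held counting noise only, so these rates leave out variation between pools. The test was also given the true scaling of the simulated libraries, with changes up or down at random. The rates therefore leave out error in the scaling of the libraries.

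Alternatives covered the column of reads on either strand, a total without the most abundant gene, lists and totals without genes whose symbol carries a copy number, totals of genes with at least 10 summed counts, other detection thresholds, TMM and DESeq2 scaling, other filters on low counts, another pseudocount and each replicate alone. After the data were seen, 2 were added: counting opposite-strand reads for the known miRNA gene on that strand, and a total without the 10 most abundant genes.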

Results

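MicroRNAs (miRNAs), small RNAs that lower the output of target mRNAs, were measured by small RNA sequencing in the neural tube of mouse embryos (strain B6NCrl) at embryonic day 11.5 (E11.5). The neural tube is the embryonic structure from which the brain and spinal cord form. The series held 1 group of 2 biological replicates, each a separate pool of male and female embryos, with 109 embryos in replicate 1 and 88 in replicate 2. RNA shorter than 30 nt was sequenced. Replicate 1 held 8530505 reads, of which 3708662 were counted on the own strand of a miRNA gene, and replicate 2 held 7655421 reads with 4055883 such counts. Abundance is given as counts per 1000000 of these own-strand counts (CPM), with mean ± SD over n = 2. There was no second tissue, stage or treatment to compare, so the data describe which miRNA genes this tissue held and how far the 2 libraries differed. A count of 0 allows up to 3 counts, which is 0.809 CPM in replicate 1 and 0.740 CPM in replicate 2. Intervals and these limits cover counting error only. How evenly the libraries captured different miRNAs was not measured, so ratios between genes or lists are ratios of counts.

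Among the reads counted for a gene, miRNA genes embedded in the Hox clusters led the neural tube libraries. These clusters are the gene arrays that set position along the body axis. Reads mapped to several places were counted for no gene. They were 58.1% as many as own-strand gene counts in replicate 1 and 51.5% in replicate 2. The ranks and shares given here therefore cover only the reads counted. Mir10a (ENSMUSG00000065519.1) was the most abundant gene at 153024 ± 19766 CPM (SD, n = 2), and Mir10b (ENSMUSG00000065500.2) was next at 135923 ± 14026 CPM. Mir10a exceeded Mir10b by 1.10-fold in replicate 1 and 1.15-fold in replicate 2, but the ranges of the 2 genes over the libraries overlapped. Mir615 reached 12725 ± 1737 CPM and Mir196b reached 11059 ± 664 CPM. Together the 6 Hox cluster genes took 31.4% ± 3.25 of all counts, with 29.1% (95% Wilson interval 29.1 to 29.2) in replicate 1 and 33.7% (33.7 to 33.8) in replicate 2. Without Mir10a in the list and the total, this share was 19.0%. In the GENCODE M21 annotation of GRCm38, the assembly also called mm10, Mir10a lies on chromosome 11 from 96317165 to 96317274 on the plus strand, with no host gene annotated on that strand. Mir10b lies on chromosome 2 from 74726070 to 74726137 in introns of both Hoxd3 and Hoxd4. Mir615 lies in an intron of Hoxc5 (chromosome 15, 103014910 to 103015001), and Mir196b overlaps an exon of Hoxa9 (chromosome 6, 52230081 to 52230165).

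Genes of the miR-17 family clusters, which promote proliferation, were the next of the 15 fixed lists, with 10.2% ± 0.213 of counts. Mir17 held 44404 ± 488 CPM, Mir20a 17789 ± 894 CPM and Mir18 8420 ± 830 CPM, all in exons of the host transcript Mir17hg on chromosome 14. Mir93 (10234 ± 54.6 CPM) and Mir106b (9012 ± 407 CPM) lie inside Mcm7, a gene of the DNA replication helicase, the former overlapping an exon and the latter in an intron. The let-7 family, whose members accumulate as tissues differentiate, took 1.89% ± 0.326. The miR-17 clusters exceeded the let-7 family by 4.91-fold in replicate 1 and 6.09-fold in replicate 2. Among let-7 genes with a row used here, Mirlet7g led at 10021 ± 978 CPM, followed by Mirlet7i at 6573 ± 1705 CPM, Mirlet7d at 1066 ± 367 CPM and Mir98 at 683 ± 96.6 CPM. Mirlet7e and Mirlet7f-1 of this list had no row used here. Reads on the strand opposite Gm25927, where Mirlet7e lies, came to 3306 ± 859 CPM and are left out of these values. Of the 10 members measured, 5 shared a run of at least 20 nt with another hairpin, so their reads could fall among those mapped to several places, which were counted for no gene. The share and the ratio cover only the reads counted.

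Outside these groups, the abundant genes were Mir99a and Mir100, 2 members of the miR-99 family, at 70859 ± 10395 CPM and 29876 ± 4353 CPM. Mir99a lies in an intron of the noncoding Mir99ahg (chromosome 16, 77598936 to 77599000). Mir335, in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), held 46427 ± 1152 CPM. Mir130a (27116 ± 5.97 CPM), the endothelial gene Mir126a (23624 ± 1869 CPM), Mir99b (21920 ± 805 CPM), Mir30e (18137 ± 1718 CPM) and the X-linked Mir322 (17026 ± 1957 CPM) followed. Of the 25 most abundant genes, each at 8015 CPM or more on average, 19 had a host gene on the same strand, 13 lay in a protein-coding gene and 7 overlapped an exon. These 25 genes held 71.0% of counts in replicate 1 and 75.9% in replicate 2. Mir23b and Mir487b were the 2 of them that shared a run of 20 nt with another hairpin, and their counts are less certain for that reason.

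Genes known as neural took 1.04% ± 0.107 of counts, less than the Hox cluster genes by 26.1-fold in replicate 1 and 35.0-fold in replicate 2. Mir92b, abundant in neural progenitors, led the list at 4979 ± 383 CPM. Mir137, which acts in neuronal differentiation, held 1965 ± 289 CPM, Mir125b-1 1080 ± 168 CPM and Mir153, in an intron of Ptprn2, 782 ± 116 CPM. Of the 17 neural genes measured, 13, Mir125b-1 among them, shared at least 20 nt with another hairpin. Reads mapped to several places formed 25.2% of all reads in replicate 1 and 27.3% in replicate 2 and were counted for no gene, so this share and its ratios to other lists cover only the reads counted. The glial and late neuronal list took 0.805% ± 0.159, most of it from Mir219a-2, known from oligodendrocyte differentiation, at 7100 ± 1480 CPM. Without genes whose symbol carries a copy number, Mir219a-2 included, that list took 0.0305%. Mir219a-1 held 390 ± 26.7 CPM, Mir138-1 175 ± 28.6 CPM and the activity-dependent Mir132 108 ± 13.9 CPM. Mir219a-1 and Mir219a-2 share 22 nt, and Mir138-1 shares 24 nt with its second copy.

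The Dlk1-Dio3 cluster, a large imprinted array on chromosome 12, took 5.18% ± 0.664 of counts over 47 genes. Its leading members among genes with a row used here were Mir487b at 8015 ± 1109 CPM, Mir411 at 5913 ± 1314 CPM, Mir431 at 4621 ± 928 CPM and Mir541 at 3928 ± 1136 CPM. Mir411 shares 21 nt with Mir758. Reads on the strand opposite Gm24321, where Mir409 of this cluster lies, came to 5826 ± 631 CPM and are left out of these values. The Sfmbt2 cluster, best known from placenta, took 0.556% ± 0.0155, with Mir467d at 1798 ± 65.8 CPM, Mir467c at 1323 ± 248 CPM, Mir467e at 1178 ± 75.4 CPM and Mir669l at 524 ± 27.7 CPM. Since 67 of its 69 genes shared a run with another hairpin, single genes of this cluster are uncertain, and 59 of the 69 lie on chromosome 2, where Sfmbt2 is. The pluripotency list took 0.169% ± 0.00246, led by the neighbours Mir302a (582 ± 76.1 CPM), Mir302d (532 ± 13.7 CPM), Mir302b (438 ± 47.7 CPM) and Mir302c (74.5 ± 5.49 CPM), with 20 nt shared by Mir302a and Mir302b. The list of an X-linked cluster known from testis had 26 counts in replicate 1 and 36 in replicate 2 over 20 genes. Its share was 0.000701% (95% Wilson interval 0.000478 to 0.00103) and 0.000888% (0.000641 to 0.00123), and its leading gene Mir741 held 2.93 ± 1.09 CPM. Of these genes, only Mir741 had at least 10 summed counts, and with that filter the share was 0.000293%.

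Markers of other cell types that the dissection could hold ranged from 2.70% of counts for epithelial and sensory genes to 0.0362% for liver, gut and endocrine genes. Mir126a, a gene of endothelial cells that overlaps an exon of Egfl7 (chromosome 2, 26591357 to 26591429), held 23624 ± 1869 CPM, or 2.36% ± 0.187 of counts. The counts of this gene, which shares no run with another hairpin, exceeded those of the neural list by 2.24-fold in replicate 1 and 2.32-fold in replicate 2. These ratios are upper values to the extent that reads of the neural copies were counted for no gene. The epithelial and sensory list took 2.70% ± 0.144, chiefly from Mir182 (11279 ± 295 CPM), Mir183 (8462 ± 1127 CPM) and Mir96 (3433 ± 297 CPM), a cluster known from sensory organs, with the epidermal Mir203 at 1678 ± 17.5 CPM. The mesenchyme list took 2.12% ± 0.452, led by Mir214 (9943 ± 2793 CPM), Mir143 of smooth muscle (5789 ± 761 CPM) and Mir140 of cartilage (4821 ± 889 CPM), with Mir199b at 380 ± 40.8 CPM. Mir199b shares 29 nt with the Mir199a genes. Muscle genes took 0.122% ± 0.0377, less than the neural list by 7.51-fold in replicate 1 and 10.1-fold in replicate 2. Among them, the skeletal muscle gene Mir206 held 1060 ± 423 CPM, the cardiac gene Mir208b 98.2 ± 53.9 CPM, Mir133b 36.2 ± 4.84 CPM and Mir499 14.7 ± 5.85 CPM. Mir133b shares 21 nt with the Mir133a genes, and as 4 of the 9 muscle genes share a run, the muscle share also covers only the reads counted. Blood genes took 0.0886% ± 0.0200, with the erythroid genes Mir451a at 418 ± 101 CPM and Mir144 at 25.7 ± 6.36 CPM, the myeloid Mir223 at 229 ± 53.4 CPM and Mir155 at 189 ± 34.2 CPM. Reads on the strand opposite Mir142b, where Mir142 of this list lies, came to 481 ± 89.4 CPM and are left out of these values. In the counts of either strand, which include those reads, the blood share was 0.134%. The liver, gut and endocrine list took 0.0362% ± 0.000278, with Mir375 at 224 ± 2.40 CPM, Mir192 at 73.7 ± 4.11 CPM, Mir194-2 at 54.7 ± 4.19 CPM and the liver gene Mir122 at 7.85 ± 0.0497 CPM. Mir194-2 shares 22 nt with Mir194-1. With n = 2 the smallest two-sided p a permutation test of list against list allows is 0.5, so the order of lists rests on both libraries giving it. Without genes with a copy number, glial and late neuronal (0.0305%) stood below Sfmbt2, pluripotency, muscle, blood and liver, gut and endocrine (0.0316%). Blood stood above muscle in the counts of either strand, at 0.134% against 0.119%. With opposite-strand reads counted for the known gene, chosen after seeing the data, blood stood above muscle by the same values and let-7 (2.18%) above mesenchyme (2.08%).

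**Figure D1:**
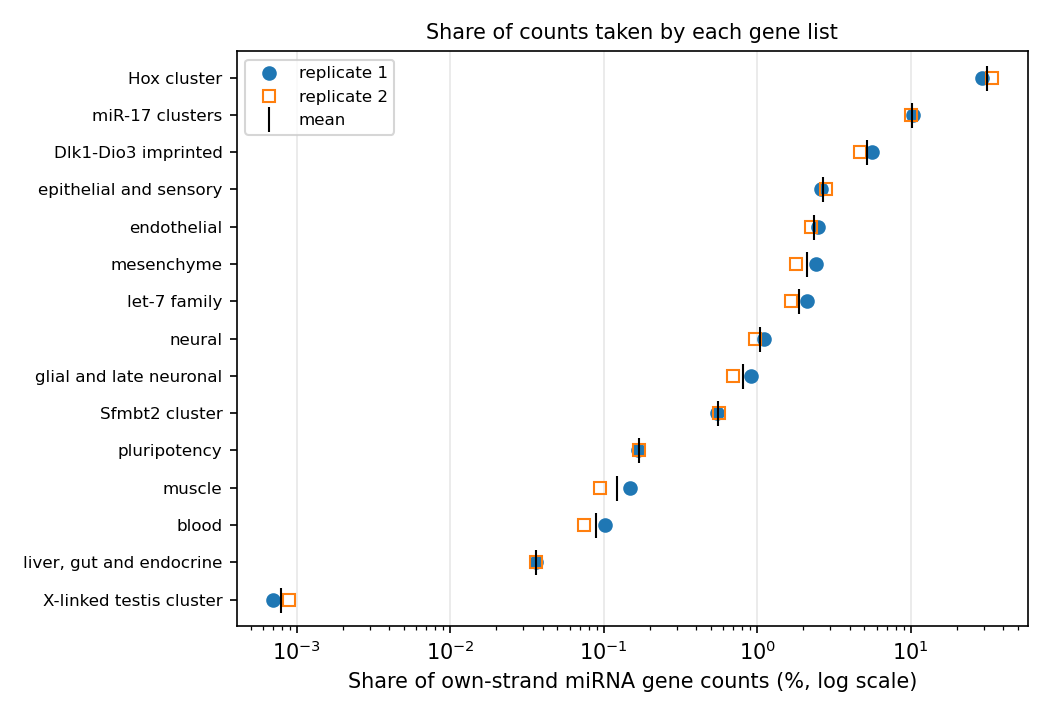
Share of own-strand miRNA gene counts taken by each of the 15 gene lists in the 2 E11.5 neural tube libraries, in percent on a log axis. Filled circles are replicate 1, open squares replicate 2 and bars the mean, and the lists run from 31.4% for the Hox cluster genes to under 0.001% for the X-linked testis cluster.

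The 2 libraries were close in rank and level. Of 1973 miRNA genes, 372 had at least 10 counts in both libraries, 89 had at least 1000 CPM in both and 1249 had no count in either. A threshold of 1 count in both gave 583 genes. Across the 444 genes with at least 10 summed counts, Pearson's r of log2(CPM + 1) was 0.993 and Spearman's rho 0.987, a description across genes, which are not independent replicates. The most abundant 10 genes held 54.1% of counts in replicate 1 and 60.2% in replicate 2, and the most abundant 50 held 85.8% and 88.0%. Mir10a, Mir10b, Mir99a and Mir100 were higher in replicate 2 by 1.20-fold, 1.16-fold, 1.23-fold and 1.23-fold. Scaled by total counts, the median gene was higher in replicate 1 by 0.27 on the log2 scale. Of 272 genes with at least 200 summed counts, 256 lay within 1.5-fold of equality after the median of these 272 genes was subtracted.

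**Figure D2:**
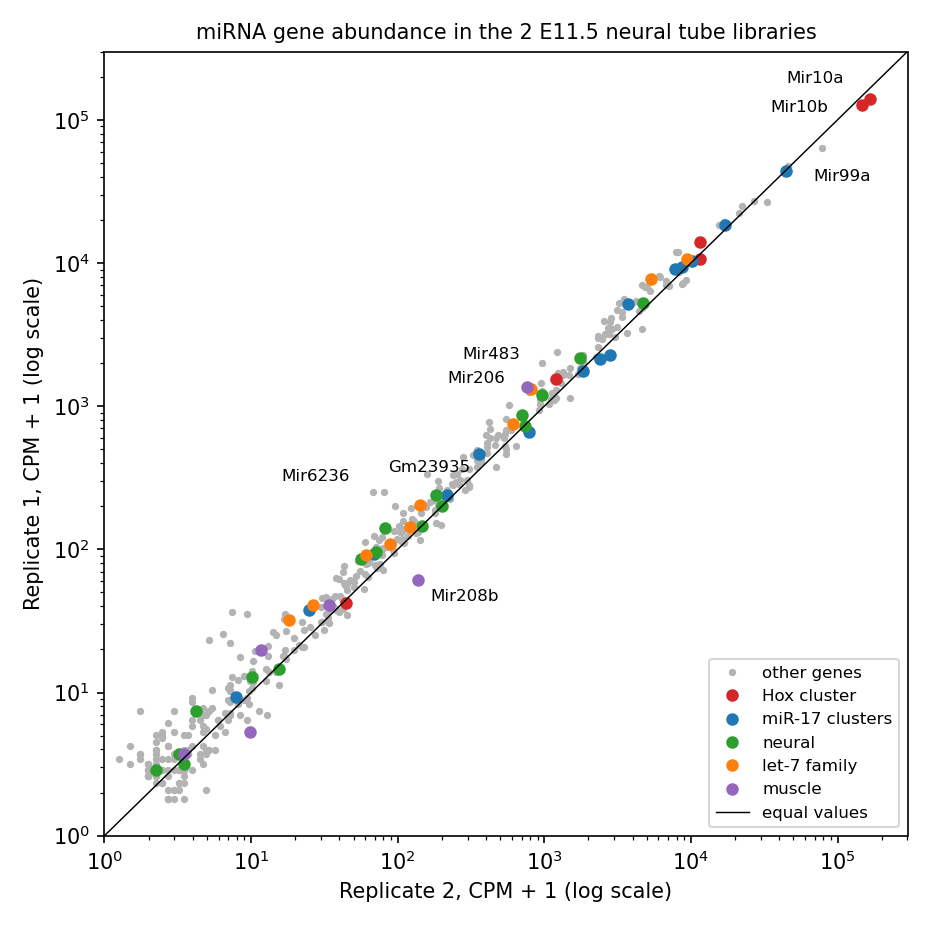
CPM + 1 of the 444 miRNA genes with at least 10 summed counts, replicate 2 on the x axis and replicate 1 on the y axis, both on log scales, with 5 gene lists coloured and equal values marked by the line. Most genes lie slightly above the line, Mir10a, Mir10b and Mir99a lie below it, and Mir6236 and Gm23935 stand above their neighbours, by 3.78-fold and 3.14-fold between libraries.

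The genes that set the libraries apart most were few. Among genes with a mean of at least 100 counts, 5 were at least 2-fold higher in replicate 1 and 1 was at least 2-fold higher in replicate 2, by a two-sided exact binomial test with Benjamini-Hochberg adjustment. Mir6236 was 3.78-fold higher in replicate 1 (exact binomial adjusted p = 1.54e-98), with 935 counts against 270. Gm23935, which shares 57 nt with other hairpins and is uncertain as a single gene, was 3.14-fold higher (exact binomial adjusted p = 4.45e-79). Mir449a, a gene of multiciliated cells in an intron of Cdc20b, was 2.14-fold higher (exact binomial adjusted p = 2.98e-57). Mir493 of the Dlk1-Dio3 cluster was 2.12-fold higher (exact binomial adjusted p = 6.58e-34), and Mir483, in an intron of the imprinted growth factor gene Igf2, 2.08-fold higher (exact binomial adjusted p = 1.12e-311). Mir208b, in an intron of the myosin gene Myh7, was 2.26-fold higher in replicate 2 (exact binomial adjusted p = 2.79e-26). With TMM scaling (trimmed mean of M values) these 6 kept their direction, but Mir449a, Mir493 and Mir483 fell to 1.76-fold, 1.73-fold and 1.70-fold.

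In all, 236 of the 444 genes differed between the libraries, 201 higher in replicate 1 and 35 higher in replicate 2, and 24 of them by at least 2-fold, or 12 among genes with at least 100 summed counts. TMM scaling moved all log2 ratios by -0.29 and gave 175 genes, 79 higher in replicate 1 and 96 in replicate 2, with 13 by at least 2-fold. DESeq2's size factors gave 180 genes, 85 and 95, with 14 by at least 2-fold, and the total without the 10 most abundant genes, chosen after seeing the data, gave 182 genes, 109 and 73, with 15 by at least 2-fold. Under all 4 scalings, 79 genes were higher in replicate 1 and 35 in replicate 2. The test compares these 2 libraries, not conditions, and takes reads as independent, so PCR copies make its p-values too small. The common dispersion of edgeR put the spread between the 2 libraries beyond counting error at a coefficient of variation of 17.6%.

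The let-7 family and the Dlk1-Dio3 cluster lay toward replicate 1 of the other genes, and the Hox cluster and Sfmbt2 cluster genes toward replicate 2. The median log2 ratio of replicate 1 over replicate 2 was 0.53 for the 10 let-7 genes, at percentile 98.9 among 10000 random lists of matched abundance (95% range 0.06 to 0.49). It was 0.37 for 44 Dlk1-Dio3 genes, at percentile 99.1 (0.18 to 0.36). It was -0.09 for the 6 Hox cluster genes, at percentile 1.92 (-0.08 to 0.45), and -0.06 for 12 Sfmbt2 cluster genes, at percentile 0.55 (-0.0014 to 0.53). With at least 100 summed counts, the Hox cluster moved to percentile 5.36 and the Sfmbt2 cluster to 8.06, both inside the random range. The other 9 of the 13 lists with at least 3 tested genes lay inside it, from percentile 6.28 for liver, gut and endocrine to 83.9 for blood. At 100 or more summed counts, the liver, gut and endocrine list stood at 1.29. Only Mir375, Mir192 and Mir194-2 were then left in it, and its median stayed at -0.02. The percentiles describe these 2 libraries and were not adjusted for the number of lists. Random lists drew single genes from all tested genes. Their ranges therefore leave out any tie between members of the same cluster or between hairpins that share sequence.

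Gene by gene, all 10 let-7 genes tested were higher in replicate 1, among them Mirlet7d by 1.64-fold and Mirlet7i by 1.45-fold, but with TMM scaling 5 were higher in replicate 1, 1 in replicate 2 and 4 did not pass. Of the Dlk1-Dio3 genes, 30 were higher in replicate 1, 2 in replicate 2 and 12 did not pass, against 17, 10 and 17 with TMM scaling. Mir541 was 1.51-fold and Mir411 1.37-fold higher in replicate 1, and Mir487b 1.22-fold higher in replicate 2, each in the same direction with TMM scaling. Of the Hox cluster genes, 2 were higher in replicate 1, 3 in replicate 2 and 1 did not pass, and TMM scaling gave 1, 3 and 2. Of the miR-17 cluster genes, 7 were higher in replicate 1 and 5 in replicate 2, against 1 and 9 with TMM scaling. Of the Sfmbt2 cluster genes, 4 and 3 passed in these directions, against 1 and 5. Of the neural genes, 8 of 17 were higher in replicate 1 and none in replicate 2, against 2 and 4 with TMM scaling. Of the glial and late neuronal genes, 6 of 9 were higher in replicate 1, against 1 with TMM scaling and 2 higher in replicate 2. Of the 9 pluripotency genes tested, 4 were higher in replicate 1 and 1 in replicate 2, against 1 and 3. Over all 444 genes tested, 201 were higher in replicate 1 and 35 in replicate 2, against 79 and 96 with TMM scaling.

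The marker lists of other cell types with at least 3 tested genes lay inside the random range, and single members differed in either direction. Of 6 blood genes, 5 were higher in replicate 1 and none in replicate 2, with 2 and none under TMM scaling, and Mir451a was 1.41-fold higher. Of 7 mesenchyme genes, 6 were higher in replicate 1, 2 with TMM scaling, and Mir214 was 1.5-fold higher. Of 6 muscle genes, 2 were higher in each library, with 1 and 2 under TMM scaling. Mir206 was 1.79-fold higher in replicate 1 (exact binomial adjusted p = 2.58e-145), while Mir208b was higher in replicate 2. The endothelial gene Mir126a was 1.12-fold higher in replicate 1 by total scaling and 1.09-fold higher in replicate 2 by TMM scaling. Of 10 epithelial and sensory genes, 4 were higher in replicate 1 and 3 in replicate 2, against 1 and 5 with TMM scaling, and Mir183 was 1.21-fold higher in replicate 2. None of the 5 liver, gut and endocrine genes passed, against 2 higher in replicate 2 with TMM scaling, and the single X-linked testis gene tested did not pass under either scaling. Adjusted over the list alone, the counts of every list stayed as given by total scaling, except that 3 Dlk1-Dio3 genes were higher in replicate 2 and 5 epithelial and sensory genes in replicate 1.

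**Figure D3:**
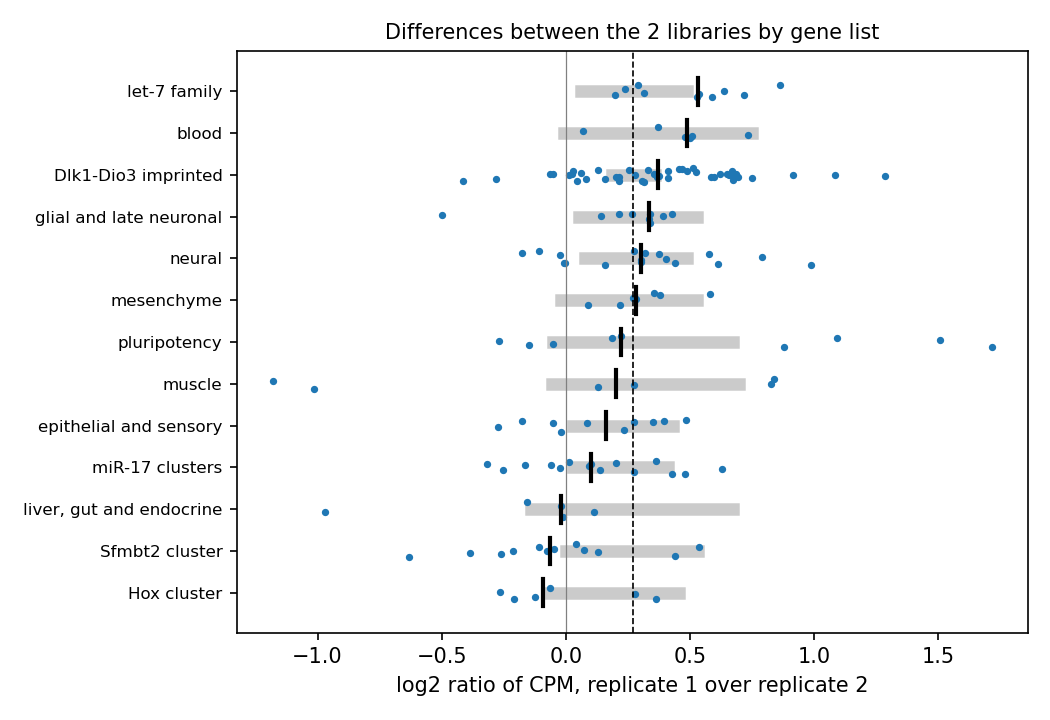
Log2 ratio of CPM, replicate 1 over replicate 2, of the tested genes (dots) of the 13 lists with at least 3 tested genes. Black bars are the medians, and grey marks the 95% range of the medians of 10000 random lists of matched abundance. The dashed line is the median of all 444 genes. By total scaling the medians run from -0.09 for the Hox cluster genes to 0.53 for the let-7 family, and TMM scaling moves every value by -0.29.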

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

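The 2 tests of opposite-strand counts in this part were chosen after the counts were seen. The report used own-strand counts, and 11 genes drew attention by holding more counts on the opposite strand than on their own, with at least 10 in both libraries, above the 3 counts that a count of 0 allows. Mean opposite-strand counts were 22542.5 for Gm24321, 12729 for Gm25927, 12073.5 for Gm25252, 6320.5 for Gm24083, 6160 for Mir299b, 6103 for Gm25301, 4459 for Gm25750, 1855 for Mir142b, 947 for Mir497b, 69.5 for Gm25641 and 32.5 for Gm24111. These 11 genes held 99.6% of all opposite-strand counts in replicate 1 and 99.7% in replicate 2, and opposite-strand counts were 2.12% and 1.69% as many as own-strand counts.

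Against imperfect strand marking of the libraries, the 25 most abundant genes had a median of 0% of their counts on the opposite strand and a highest value of 0.0114%. A known miRNA gene lies on the other strand of the counted gene in all 11 cases, or 100%, against 1.12% of 1883 other genes. The counts are therefore consistent with reads of these partners, which had no row used here: Mir409, Mirlet7e, Mir376a, Mir191, Mir299a, Mir378a, Mir380, Mir142, Mir497, Mir9-1 and Mirlet7f-1, in the order of the genes above. Other transcripts of the partners' strand were not tested, and no biological explanation was tested, since the design gives none.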

How the results depend on the processing

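Detected genes were 383 without replicate 1 and 391 without replicate 2. With n = 2 each library lies within 1 SD of the mean by construction, so leaving out a replicate says nothing about the stability of shares, abundances and concentration (the plot of list shares shows each library). The comparison of libraries, the list shift and the correlation need both libraries and have no such value. No paired analysis was possible because there is a single group. The count of genes that differ stayed within 1.5 times of 236 under 6 alternatives, from 175 to 245, but their direction did not hold. Of the genes that passed, 85.2% were higher in replicate 1 by total scaling, against 45.1% with TMM scaling and 47.2% with DESeq2's size factors. The cause of the changes here and below was not tested beyond what each alternative's construction shows. Depth limits genes of low count, and at 1.5-fold the test found 69% of simulated changes against 98.4% at 200 counts or more.

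A total without Mir10a, which also left the Hox list, gave 1.23% for neural, 19.0% for Hox cluster, 2.22% for let-7, 0.200% for pluripotency, 12.1% for miR-17 clusters, 6.10% for Dlk1-Dio3, 2.79% for endothelial, 3.20% for epithelial and sensory, 0.0428% for liver, gut and endocrine, 0.000940% for X-linked testis and 0.657% for Sfmbt2, with 51.5% in the most abundant 10 genes and 84.9% in 50. Without genes with a copy number, neural took 0.810%, glial and late neuronal 0.0305%, pluripotency 0.174% and liver, gut and endocrine 0.0316%, with 88.8% in 50 genes. The column of either strand gave 0.166% for pluripotency, 0.134% for blood and 0.0356% for liver, gut and endocrine. Counting opposite-strand reads for the known gene, an alternative chosen after seeing the data, gave 0.166% for pluripotency, 6.23% for Dlk1-Dio3, 0.134% for blood and 0.0355% for liver, gut and endocrine. Totals of genes with at least 10 summed counts gave 0.000293% for X-linked testis. Of named-gene CPM values, 46 moved by more than 1 SD without Mir10a in the total, 10 without copy-number genes and 6 with either strand.

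At 1 count in both libraries, 583 genes were detected. At least 2-fold differences were found for 13 genes with TMM, 14 with DESeq2's size factors, 12 with at least 100 summed counts and 15 with the total without the 10 most abundant genes, the last chosen after seeing the data. With at least 100 summed counts, the Hox cluster stood at percentile 5.36 and Sfmbt2 at 8.06, no longer outside the random range. Liver, gut and endocrine stood at 1.29, outside it, a value that rested on Mir375, Mir192 and Mir194-2 alone. For every gene with at least 1 count, Spearman's rho was 0.943.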

Other observations

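The test of shared copies in this part was chosen after the counts were seen, and the others were fixed before. Among pairs of clustered genes picked after their values were seen, some were close in abundance and others far apart. Mir182 exceeded Mir183 by 1.44-fold in replicate 1 and 1.24-fold in replicate 2, and Mir183 exceeded Mir96 by 2.38-fold and 2.54-fold. Within the Mir17hg transcript, Mir17 exceeded Mir20a by 2.39-fold and 2.61-fold, and exceeded Mir19a by 479-fold in replicate 1 and 655-fold in replicate 2, with Mir19a at 80.1 ± 16.7 CPM (SD, n = 2). Mir143 exceeded its neighbour Mir145a, also of smooth muscle, by 45.7-fold and 48.5-fold, with Mir145a at 123 ± 21.3 CPM. Mir99a exceeded Mir125b-2, which lies in the same host Mir99ahg, by 88.1-fold and 107-fold, and exceeded Mirlet7c-1 of that host by 586-fold and 899-fold. Mir206 exceeded the neighbouring Mir133b by 34.3-fold and 23.2-fold. Mir125b-2 shares 24 nt, Mirlet7c-1 23 nt and Mir133b 21 nt with other hairpins, so these 3 ratios are uncertain. All the ratios compare counts, as how evenly the libraries captured different miRNAs was not measured. Over 100 pairs of neighbours on the same strand within 10 kb, the median difference of log2 CPM was 2.41 against 2.86 for random pairs, a ratio of 0.845 (one-sided permutation p = 0.0801), so closer abundance of neighbours was not shown.

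An X-linked cluster outside the fixed lists held Mir322 at 17026 ± 1957 CPM, Mir351 at 1806 ± 841 CPM and Mir503 at 558 ± 184 CPM, genes of a cluster known to slow the cell cycle. Mir322 exceeded Mir351 by 7.67-fold in replicate 1 and 12.9-fold in replicate 2. Mir351 was 1.98-fold higher in replicate 1 and Mir503 1.61-fold higher, with 1.62-fold and 1.32-fold by TMM scaling. Mir363 of another X-linked cluster, a miR-17 cluster member, held 2267 ± 184 CPM.

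Copies of Mir9 and Mir124a, the best known miRNAs of the nervous system, had few counts, with Mir9-3 at 200.1 ± 0.458 CPM and Mir124a-2 at 10.5 ± 1.94 CPM. Reads shared between near-identical copies are a candidate explanation: in the neural list, 13 genes that share at least 20 nt with another hairpin had a median of 69.6 CPM, against 1240 CPM for the 4 others, and in the let-7 list 5 such genes had a median of 74.7 CPM, against 1066 CPM for the other 5. These lists prompted the explanation, so it was tested on the other 10 lists with at least 2 sharing and 2 other genes. There the mean difference of medians, sharing minus not sharing, was -2.05 on the log2(CPM + 1) scale (one-sided permutation within lists, p = 0.0168), and -2.51 (p = 0.0085 by the same permutation) over the 8 lists with a median above the level of 3 counts. Of these 8, sharing genes had a lower median in 5 and a higher one in 3, glial and late neuronal, pluripotency and Dlk1-Dio3. The permutation took genes as independent. Sharing genes of the same list can share sequence with each other, as Mir199b and the Mir199a genes do, so both p-values can be too small. How many reads mapped to several places belong to these genes was not analysed here, and low expression of some copies stays open.

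For the genes that differ between the 2 libraries, 3 explanations were tested. GC content of the hairpin, a stand-in for that of the reads, had a Spearman rho of 0.0251 with the log2 ratio over 301 genes (95% bootstrap interval -0.0909 to 0.144), far from the 0.5 set in advance. A few abundant genes taking most of the counts were not the whole cause, as 175 genes passed with TMM scaling against 236 by the total. Under all 4 scalings, 79 genes passed as higher in replicate 1 and 35 as higher in replicate 2. TMM scaling alone gave the same 79 and the total alone the same 35. Each scaling shifts all log2 ratios by the same amount, so this overlap adds no separate support. Without the 10 most abundant genes in the total, an alternative chosen after seeing the data, 59.9% of the genes that passed were higher in replicate 1, against 85.2% by the total. A difference between the pools in the transcripts made could not be decided, as neighbours within 10 kb differed in their log2 ratio 0.949 times as much as random pairs (one-sided permutation p = 0.3227, 100 pairs). The labels give no batch, and pools of different litters, dissections or library preparations cannot be told apart with 1 library each. Unmapped reads were 24.5% of reads in replicate 1 and 15.2% in replicate 2. Mapped reads on no gene's own strand, opposite-strand reads included, were 6.83% and 4.49%. Whether these differences bear on the genes or lists that differ was not tested.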
